A study of Mus musculus with 4 samples.

How the data were processed

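Adrenal gland RNA of wild-type and V1a knockout male mice, 2 months old, was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 2 samples per genotype and 1 array per sample. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was purified from it, only samples with an RNA integrity number from 8.0 to 9.0 went into labelling, and the arrays were read on a GeneChip Scanner 3000. The deposited values are log2 expression values per probe set, made by the authors with the GCRMA package in Bioconductor 3.14, per the labels' protocols and the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalizes between arrays and summarises the probes of a probe set, so weak probe sets gather near a shared floor, here 2.30, and differences of genes near it are compressed. The scale is not written in the table and was read from the values, which ran from 2.30 to 14.9, as the plan for the tests had assumed. The version of GCRMA and any probe filter are not given in the sources used here.

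No further normalization was applied. The medians of the tested probe sets on the 4 arrays were 7.11, 6.99, 7.03 and 7.03. The 64 control probe sets of the manufacturer were left out, and a probe set was tested if it reached 4 log2 units on at least 2 of the 4 arrays, whichever they were. No 2 arrays held the same values: 1.09% to 1.65% of tested values were identical between any 2 arrays. Genes were named from the platform annotation and checked against the gene table of GRCm38.p6 through the gene ID, where 34741 probe sets matched and 0 symbols changed. Of 45037 probe sets, 34945 had 1 gene, 932 several and 9160 none, and no gene was named from a probe set with several. Of the tested ones, 15890 had 1 gene, 497 several and 841 none. For results per gene, the probe set with the highest mean over the 4 arrays stood for its gene, which gave 10110 genes, 3861 of them with more than 1 tested probe set. Chromosomes and distances between genes came from the mouse assembly GRCm38.p6, which gave a place to 10088 of these genes. The array values carry no genome build.

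Groups were taken from the genotype in the labels. Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, genotype only), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The fit had 2 residual and 1.73 prior degrees of freedom, and the median residual SD was 0.263. A second, unadjusted threshold, p under 0.01 with at least a 2-fold difference, was fixed because 2 arrays per group leave few degrees of freedom. Each SE is limma's moderated standard error of the difference, and each SD is over the 2 arrays of a genotype. The number of arrays limits the precision.

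32 gene lists of 619 genes were fixed for adrenal cell types, pathways and neighbouring tissues, and 560 of these genes were named on the array. The 25 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. With an estimated correlation in camera 0 lists passed (smallest adjusted p 0.902), and with fry, which asks only whether a list's genes move one way on balance, 0 passed (smallest adjusted p 0.164). Camera with an estimated correlation tests on the 2 residual degrees of freedom, which leaves it little power. A call lost there cannot be laid to the correlation alone. Genes within 20 Mb of Avpr1a were compared with all others by a two-sided Fisher's exact test. Named in the text are Avpr1a, the 12 genes in each direction with the largest adjusted calls or, failing those, the smallest unadjusted p among genes at least 2-fold apart, and for each list up to 6 members past the threshold, otherwise the 2 with the smallest p. Star, Cyp11a1, Cyp11b1, Cyp11b2, Cyp21a1, Th, Dbh and Pnmt were named whatever their p. Genes named outside this rule were chosen after their values were seen: Avpr1b, Avpr2, Akr1c18, Alb, Apoa1, Ttr, Ggps1, Sqle, Cyp51, Hsd17b7, Fdft1, Nr0b1, Eif2s3y, Xist, Xaf1, Adi1, Kcnmb4, Nnt, Cap1, Ppt1, Tmem267, Lpcat2, Sdc4 and Cd59a. The grouping, the tests, the lists, the naming rule and all alternatives were fixed before the data were examined.

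The alternatives were no filter, a filter at 6 log2 units, quantile normalization, centring each array on its median, eBayes with trend and robust, plain probe sets only, the replicate number as a block, leaving out each array in turn, limma's test against a 2-fold difference, 1 probe set per gene, the mean of a gene's probe sets, an estimated correlation or fry for the lists, and windows of 5 and 40 Mb. The scripts were tested on simulated data for the comparison of knockout with wild type. With 17228 probe sets and the spread of these arrays, 200 of them changed by known amounts in each of 10 runs, the adjusted threshold called 0%, 0.4%, 26.2% and 47.8% of changes of 1, 2, 3 and 4 log2 units, with 1.6 false calls per run. The unadjusted threshold found 27.6%, 81.8%, 89.6% and 94.4% of them, with 145.9 false ones per run. On 10110 simulated genes, camera called 0 of 250 unchanged lists and, in 10 of 10 runs, a list shifted by 1 log2 unit. The simulated genes varied independently of one another, while a correlation of 0.892 was estimated among the real adipocyte markers. The 0 of 250 thus does not cover false calls from correlated genes. Each simulated probe set also had 1 spread for all its arrays, while wild-type array 1 stood apart in the data. The strain, litter, feeding and hour of sampling of the mice are not given in the sources used here. Figures were drawn with matplotlib 3.10.9.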

Results

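Gene expression was measured in adrenal glands of male mice at 2 months of age on 4 short-oligonucleotide arrays, 2 from wild-type mice and 2 from mice that lack the V1a vasopressin receptor. The adrenal gland has an outer cortex, which makes corticosteroids from cholesterol, and an inner medulla, whose chromaffin cells make catecholamines. V1a is a receptor for vasopressin that signals through Gq and calcium. The comparison asks which adrenal transcripts differ when the receptor is missing. The values are log2 expression units, and differences are knockout minus wild type. Of 45037 probe sets, 17228 reached 4 log2 units on at least 2 arrays and were tested. The share of probe sets at or above 4 lay between 37.7% and 38.0% on the 4 arrays. The labels do not say that the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

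Avpr1a, the targeted gene on chromosome 10 (gene ID 54140), was read by 2 probe sets, both close to the lowest value of the arrays, 2.30. The first probe set of Avpr1a read 2.53 and 2.53 on the wild-type arrays and 2.53 and 2.60 on the knockout arrays, a difference of 0.03 (SE 0.03, n = 2 per group). The second read 2.31 to 2.33 on all 4 arrays, a difference of 0.01. Both lay below the filter, and the part of the gene removed in the knockout is not given in the labels, so Avpr1a does not check the genotype labels here. Avpr1b and Avpr2 were as dim, at 2.30 on every array.

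In the knockout glands, transcripts of the enzymes that build cholesterol read lower than in wild type as a group, a call that depended on the test. It passed limma's camera with a preset correlation of 0.01 (adjusted p = 3.2e-09 over 25 lists), but not with an estimated correlation of 0.0788 (adjusted p = 0.902, unadjusted p = 0.0481), with limma's fry (adjusted p = 0.248) or in camera without wild-type array 2 (median -0.84, adjusted p = 0.0850). The test with an estimated correlation has only 2 residual degrees of freedom and so little power, and its loss of the call cannot be laid to the correlation alone. Of 26 genes fixed as cholesterol synthesis and uptake, 21 were measured and 20 of them lay lower, with a median difference of -0.87. Idi1, which makes the isoprenoid building block dimethylallyl diphosphate, read 10.38 ± 0.49 (SD, n = 2) in wild type and 8.58 ± 0.28 in the knockout, a difference of -1.80 (SE 0.33). Fdps, which makes farnesyl diphosphate, went from 9.25 ± 0.03 to 7.92 ± 0.15, a difference of -1.33 (SE 0.17). Hmgcs1, which makes the HMG-CoA that enters the mevalonate pathway, differed by -1.44 (SE 0.25). Tm7sf2, Lss, Nsdhl, Hsd17b7 and Fdft1, which act at later steps towards cholesterol, differed by -1.56, -0.94, -0.87, -1.46 and -0.96. These 8 genes passed a threshold of 0.05 in limma adjusted over the list alone, with a smallest adjusted p of 0.0333 in Fdps, Hmgcs1, Idi1, Tm7sf2, Nsdhl, Lss and Hsd17b7, while 0 of the 21 passed when adjusted over all probe sets.

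The groups did not overlap in 16 of the 21 cholesterol genes, all of them lower in both knockout arrays. For 2 arrays against 2, chance gives 33.3% per gene, counting either direction and taking the arrays as interchangeable. Lists that camera did not call on the full set of arrays lay on both sides of this share. It was 7 of 8 in smooth muscle and pericytes and 20 of 34 in oxidative phosphorylation. In chromaffin cells it was 3 of 29 and in immediate-early genes 2 of 23. The share alone thus does not set the cholesterol list apart. Sqle, which makes squalene epoxide, and Cyp51, a sterol demethylase, differed by -1.26 and -1.50 and missed the threshold over the list. Ggps1 was the only member with a higher mean in the knockout, because 1 wild-type array read 3.23 and the other 7.51. The probe sets of 1 gene did not always go together: the other 3 probe sets of Hmgcs1 differed by 1.34, 0.87 and 0.26, and the other one of Idi1 by 0.78, with wild-type array 1 the lowest array on each of them.

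**Figure D1:**
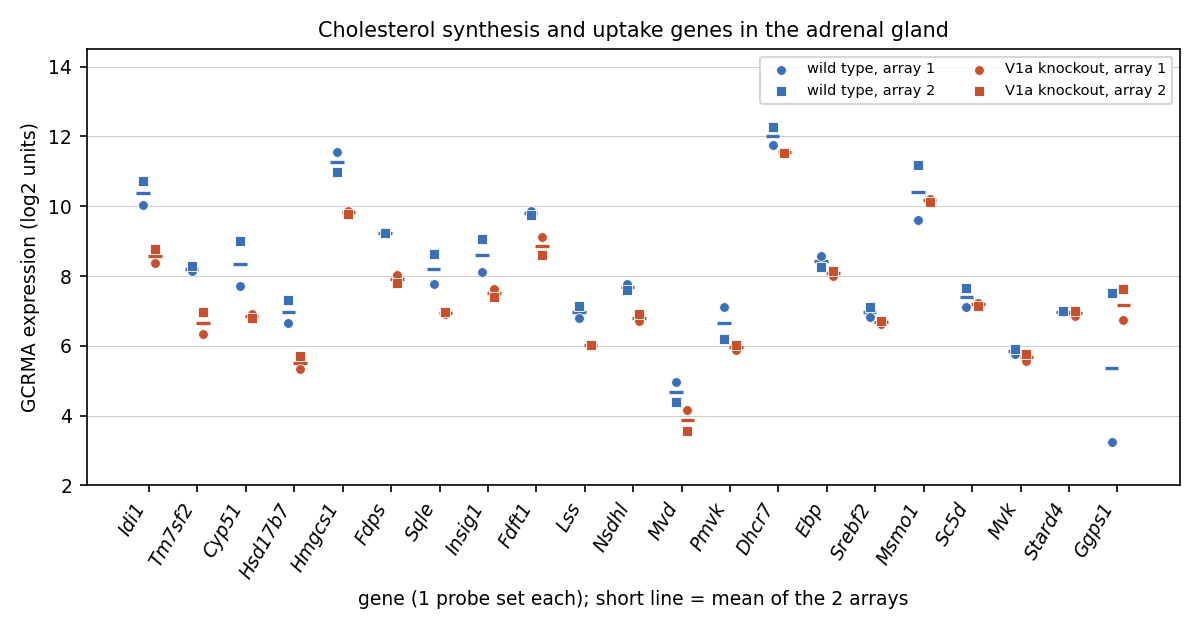
Expression in log2 units (vertical axis) of the 21 measured genes of cholesterol synthesis and uptake (horizontal axis), with 1 point per array and a short line at the mean of the 2 arrays of each genotype. In 16 genes both knockout arrays lie below both wild-type arrays, and in Ggps1 wild-type array 1 lies apart at 3.23.

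Genes that handle stored and imported cholesterol did not share this direction. Plin2, which coats lipid droplets, was 11.04 ± 0.12 in the knockout and 9.86 ± 0.15 in wild type, a difference of 1.18 (SE 0.18, limma adjusted p = 0.0563 when adjusted over the list alone). Npc1, which moves cholesterol out of lysosomes, differed by 0.84 (SE 0.19). Of the 15 measured genes of cholesterol ester and lipid droplet handling, 7 lay higher and 8 lower, and the median was -0.16, while camera gave the opposite sign (upward, adjusted p = 0.389). The groups did not overlap in 8 of the 15, with both knockout arrays higher in 6 and lower in 2.

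The enzymes that turn cholesterol into steroids gave small differences, some of them from probe sets near the top of the scale (array maxima 14.7 to 14.9), where differences can be compressed. Star, which brings cholesterol into mitochondria, read 14.17 ± 0.08 in wild type and 14.20 ± 0.04 in the knockout, and Cyp11a1, which cuts its side chain, 13.96 ± 0.07 and 13.97 ± 0.04. Cyp11b1 and Cyp21a1, enzymes of corticosterone synthesis, differed by 0.11 (SE 0.19) and -0.12 (SE 0.19), and Cyp11b2, the aldosterone synthase, by 0.18 (SE 0.27). The steroidogenesis list had a median of -0.12 over 14 genes, 0 of them at an unadjusted p under 0.05, and its lowest p values belonged to Nr5a1 at -0.37 and Mrap at -0.45 (camera adjusted p = 0.389). In the list of zona glomerulosa and aldosterone genes, the median was 0.00 over 16 genes, with Vsnl1 at 0.52 and Rspo3 at -1.37. Genes of the renin-angiotensin system had a median of 0.08 over 8 genes, with Ace at -0.59 and Agtr1a at 0.44. The 3 fixed genes of the X-zone, an inner cortical layer of young mice, were too dim to test, and Akr1c18, its usual marker, read 2.30 to 3.11.

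Signalling and medullary genes gave no shift that passed camera on all 4 arrays. The vasopressin and Gq signalling list had a median of -0.05 over 17 genes, with Camk2d at 1.85 and Rgs5 at 0.52, and the ACTH and cAMP signalling list a median of -0.01 over 19 genes, with Prkar1a at 0.42 and Adcy9 at 0.83. In chromaffin cells of the medulla, 14 of 29 genes lay higher and 15 lower, with a median of -0.02. Th, Dbh and Pnmt, which act in turn on the way to adrenaline, differed by -0.02 (SE 0.45), -0.30 (SE 0.72) and -0.77 (SE 0.71), and the smallest p values belonged to Penk at -0.88 and Insm1 at 1.76. Medulla genes as a list also varied within a genotype, with a median of 0.85 between the wild-type arrays and 0.71 between the knockout arrays, and passed camera in opposite directions without knockout array 1 (-0.35, adjusted p = 0.0104) and without knockout array 2 (0.34, adjusted p = 0.00218). These calls rest on the preset correlation of 0.01, where 0.700 was estimated for the list on all 4 arrays (adjusted p = 0.988 in camera with it).

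Among lists of cell state, antigen presentation came nearest to the threshold. Of its 14 measured genes 13 lay lower, with a median of -0.27, H2-K1 at -0.78 and Tap1 at -0.87 (camera adjusted p = 0.0641). Without wild-type array 1 its median was -0.02, and without wild-type array 2 -0.64 (camera adjusted p = 0.0209 at the preset correlation, where 0.686 was estimated on all 4 arrays, with an adjusted p of 0.902). Oxidative phosphorylation had 25 of 34 genes lower and a median of -0.21, with Ndufa4 at -0.90 and Uqcrq at -0.69 (camera adjusted p = 0.0863), and leaving out each array in turn gave medians of -0.37 to -0.09. Heat shock genes had a median of -0.25, with Hsph1 at -0.79 and Hspb1 at -0.67, glutathione and antioxidant genes -0.25, with Txnrd1 at 0.69 and Gclm at -0.62, and the unfolded protein response -0.06, with Calr at -0.68 and Asns at -0.67. Leaving out each array in turn moved the heat shock median between -0.62 and -0.06 and the antioxidant median between -0.45 and -0.09. Immediate-early genes had a median of -0.30, with Junb at -2.76 and Gadd45b at -1.39, beside a median of 1.98 between the 2 wild-type arrays. The medians of fatty acid oxidation (Etfdh 0.27, Acadl 0.26), the circadian clock (Arntl 0.83, Tef -0.62), the cell cycle (Mki67 -0.72, Mcm2 0.57) and interferon-stimulated genes (Irf9 0.63, Gbp3 1.08) were 0.06, 0.03, 0.09 and 0.03. The interferon-stimulated list turned from a median of 0.45 without wild-type array 1 (camera adjusted p = 0.000117 at the preset correlation, where 0.432 was estimated on all 4 arrays) to -0.47 without wild-type array 2 (camera adjusted p = 0.828).

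Markers of other cells in the gland did not pass camera on all 4 arrays. Medians were 0.10 for macrophages (Ctss 0.83, Cd68 1.11), 0.01 for endothelium (Sox18 0.67, Ptprb -0.69), -0.13 for capsule and fibroblasts (Postn -0.67, Dcn from a mean of 10.10 to 9.10), -0.34 for smooth muscle and pericytes (Des -0.46, Acta2 -0.72) and -0.08 for Schwann and glial cells (Sox10 -0.81, Fabp7 -0.61). Macrophage markers passed without knockout array 1 (0.19, camera adjusted p = 0.00158) and capsule and fibroblast markers without knockout array 2 (-0.28, camera adjusted p = 0.0404), both at the preset correlation, where 0.457 and 0.177 were estimated on all 4 arrays (camera adjusted p = 0.902 for each). Adipocyte markers had a median of -0.14, with Slc2a4, the insulin-responsive glucose transporter, at -1.56. They passed in opposite directions without knockout array 1 (0.59, camera adjusted p = 0.0190) and without knockout array 2 (-1.17, camera adjusted p = 3.87e-10), again at the preset correlation, where 0.892 was estimated on all 4 arrays (camera adjusted p = 0.902). Ucp1, a marker of brown fat, read 10.05 and 7.24 in wild type and 2.80 and 5.91 in the knockout. Lymphocyte (Ighm 2.10, Thy1 -0.99), erythroid (Alas2 -2.18, Bpgm -0.56), kidney (Aqp1 -0.83, Fxyd2 -0.94), liver and pancreas (Cela1 -0.39, Cpb1 0.17) and skeletal muscle (Eno3 -0.71) lists had fewer than 5 tested members and no list test. Of the liver markers, Alb read 8.86 on wild-type array 1 and 2.42 to 2.43 on the other 3 arrays. The Y-linked genes Kdm5d (0.17), Uty (0.71) and Eif2s3y (0.15) were present on all arrays, and Xist was at 2.30 on each, as the male label has it.

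Single genes with the smallest p values included some that were near the floor in 1 genotype and clearly read in the other. Serpina1b, which encodes an alpha-1 antitrypsin, read 7.97 and 7.20 in wild type and 2.30 on both knockout arrays. The difference was -5.28 (SE 0.32), and its other probe set differed by -5.08. Both have the extended suffix _x_at and are not plain probe sets, so the reading may not be of this gene alone. Tmem178 differed by -4.01 (SE 0.41), Mmp2, a gelatinase, by -2.32 (SE 0.17), Lsm12 by -2.62, Ocel1 by -2.38, Pdlim2 by -2.09, Chn2 by -2.04 and Cryba4, a lens crystallin, by -2.02. Smaller differences of this direction were read for Syce2 (-1.35), Frg1 (-1.26) and Tmem256 (-1.23). In the other direction, Rab6b, a small GTPase of vesicle traffic, read 2.61 ± 0.05 in wild type and 6.53 ± 0.27 in the knockout, a difference of 3.92 (SE 0.21). Rec8, a meiotic cohesin subunit, differed by 3.86, Galc, a lysosomal galactosidase, by 3.72, Abhd1 by 3.65, Tmem196 by 3.58, Kantr by 3.36, Zfp945 by 2.84, Rbm28 by 2.55, B3galt6 by 2.18, Acot1 by 2.06, Slc7a2, a transporter of cationic amino acids, by 1.63 and Unc45b by 1.30. None of these passed the adjusted threshold in limma, the smallest adjusted p being 0.187, in Tmem196 and in the other probe set of Serpina1b.

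**Figure D2:**
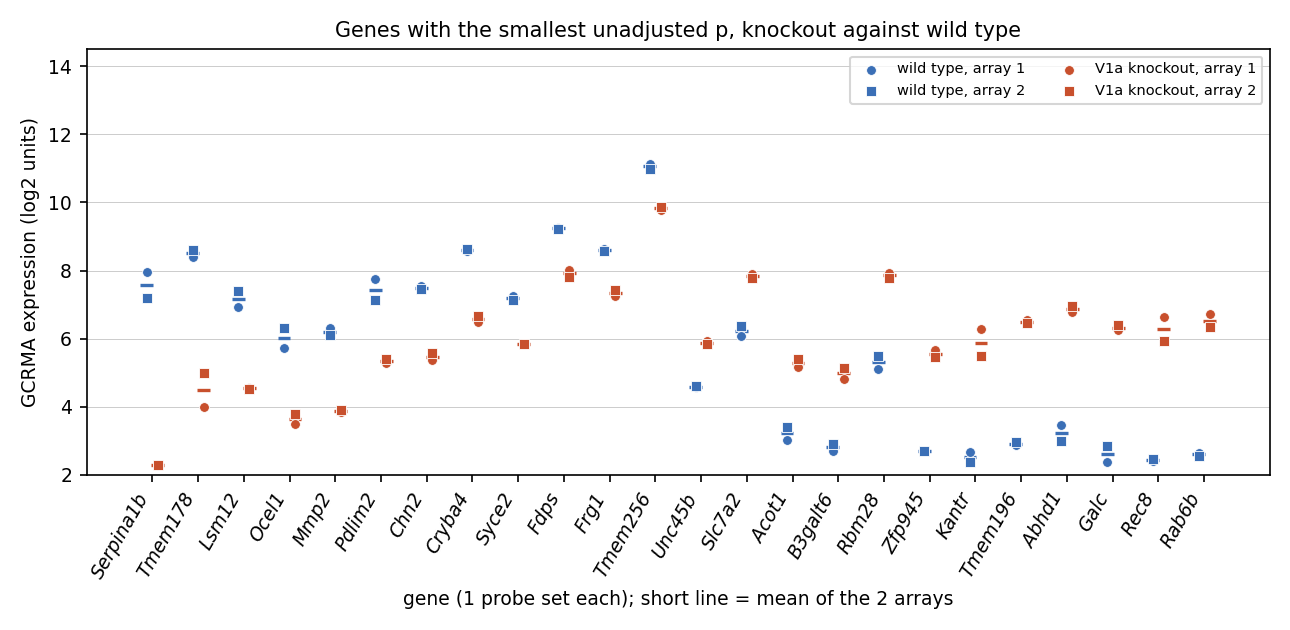
Expression in log2 units (vertical axis) of the 12 genes with the smallest p in each direction among those at least 2-fold apart (horizontal axis), with 1 point per array and a short line at the mean of the 2 arrays of each genotype. Serpina1b lies at 2.30 on both knockout arrays, and Rab6b has a wild-type mean of 2.61 and a knockout mean of 6.53, though neither gene passed the adjusted threshold.

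Over all probe sets, 0 of 17228 passed an adjusted p of 0.05 in limma, and 0 passed limma's test against a 2-fold difference. At an unadjusted p under 0.05 there were 885, where chance alone gives 861. At an unadjusted p under 0.01 with at least a 2-fold difference there were 144, of which 60 lay higher and 84 lower in the knockout, and counted as genes 70 of 10110, with 29 higher and 41 lower. Simulated arrays gave 145.9 false probe sets per run at this second threshold, and the measured count was no larger. Each simulated probe set had the same spread on all its arrays, though, while wild-type array 1 stood apart in the data. The measured count can therefore not be judged by the simulated one. Leaving out each array in turn moved it between 25 and 1497, and without wild-type array 2 the balance turned, with 1108 higher and 389 lower. The 2 lowest adjusted p values, 0.0792, belonged to single probe sets of Xaf1 at -5.90 and Adi1 at 5.20, chosen after their values were seen. Another probe set of Xaf1 differed by 1.65, and 2 others of Adi1 by 1.91 and -0.48. Both passed, with adjusted p of 0.0415 to 0.0485 in limma, under a stricter filter, quantile normalization, median centring or plain probe sets only.

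Neighbours of a targeted gene can differ because DNA of the stem cell strain stays beside it. Within 20 Mb of Avpr1a on chromosome 10, 1 of 109 genes passed the unadjusted threshold, Kcnmb4 at -1.05, against 69 of 9979 elsewhere. The odds ratio was 1.33 (95% interval 0.0329 to 7.82, two-sided Fisher's exact p = 0.534). The fixed list of genes near the locus had a median of 0.01 over 28 genes, with Mettl1 at -0.65 and Dyrk2 at 0.39.

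The arrays of 1 genotype were not always the most alike. Across tested probe sets the knockout arrays correlated at 0.986 and the wild-type arrays at 0.924, while wild-type array 2 correlated with the knockout arrays at 0.974 and 0.981. Wild-type array 1 correlated with the other 3 at 0.919 to 0.924, and the first principal component, with 73.8% of the variance, separated it from them. The second, with 18.1%, placed wild-type array 2 at -36.5, wild-type array 1 at 1.33 and the knockout arrays at 26.7 and 8.47. These correlations are across probe sets, which are not independent replicates. Without wild-type array 1, 0 probe sets passed the adjusted threshold in limma, 183 passed the unadjusted one, and the cholesterol list had a median of -0.90 (camera adjusted p = 1.62e-12 at the preset correlation). That call was lost without wild-type array 2 (adjusted p = 0.0850) and, on all 4 arrays, with an estimated correlation (adjusted p = 0.902).

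**Figure D3:**
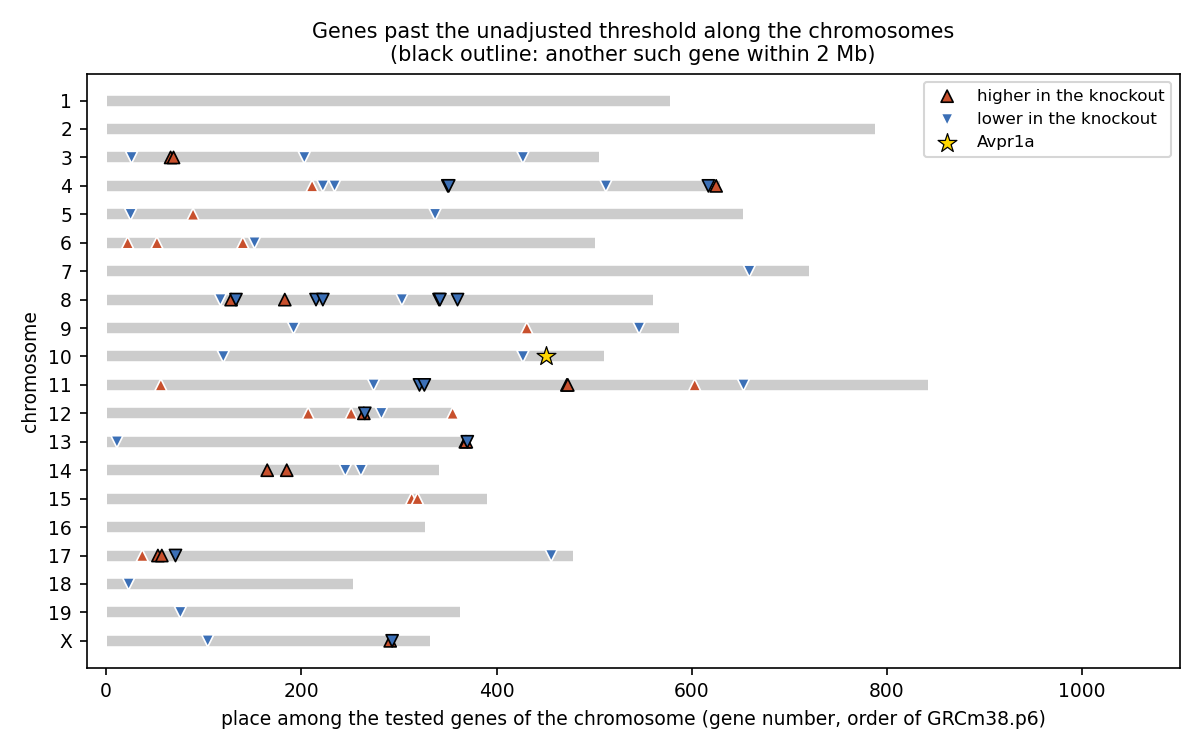
Place of the 70 genes past the unadjusted threshold among the tested genes of each chromosome (horizontal axis, gene number in chromosome order; vertical axis, chromosome), with triangles up for genes higher and down for genes lower in the knockout and a star at Avpr1a. A black outline marks the 30 genes with another such gene within 2 Mb, and chromosomes 1, 2 and 16 hold 0 of the 70.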

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

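The median of the cholesterol list stayed between -0.94 and -0.70 under all alternatives run, and camera's call held under each except an estimated correlation (-0.87, adjusted p = 0.902), fry (-0.87, p = 0.0199, adjusted p = 0.248) and without wild-type array 2, where antigen presentation (-0.64, adjusted p = 0.0209) was the 1 list called, a list with a median of -0.02 without wild-type array 1. With 1 array left in a genotype, that array is assumed to vary like the other genotype. The count of lists called was 2 without a filter and with centred arrays, 3 with a variance trend, 0 with an estimated correlation or fry, and 1 to 7 leaving out each array in turn. The lists added were oxidative phosphorylation without a filter (adjusted p = 0.00574) and with a trend (0.0278), and antigen presentation with centring (0.0358) and with a trend (0.0360). Beside the cholesterol list, leaving out wild-type array 1 added interferon-stimulated genes, and leaving out knockout array 1 added chromaffin cells, heat shock (-0.46, adjusted p = 0.0174), macrophages, antigen presentation (-0.24, adjusted p = 0.0494) and adipocytes. Leaving out knockout array 2 added chromaffin cells and adipocytes with the opposite sign, immediate-early genes (-0.55, adjusted p = 0.0365), oxidative phosphorylation (-0.28), antigen presentation (-0.29) and capsule and fibroblasts (-0.28), the last 3 at an adjusted p of 0.0404. All these calls rest on the preset correlation. The count of probe sets past the adjusted threshold was 2 under a stricter filter, quantile normalization, centring and plain probe sets, and 0 otherwise, leaving out each array included. The unadjusted count was 78 (36 higher, 42 lower) without a filter, 79 (34 and 45) on 1 probe set per gene and 94 (53 lower) on gene means, the last 2 with fewer units tested, and the stricter filter, also with fewer, gave 31 higher. Leaving out each array gave 25 to 1497 probe sets, 15 to 1108 higher and 9 to 389 lower, with 1497 without wild-type array 2, 183 without wild-type array 1, 25 without knockout array 1 and 30 without knockout array 2; the causes of these and of the count without a filter were not tested. Low signal limits Avpr1a, which differed by 0.069 after quantile normalization and by 0 to 0.065 leaving out each array. Over all probe sets, wild-type array 1 correlated at 0.979, 0.978 and 0.978 with wild-type array 2, knockout array 1 and knockout array 2, a difference whose cause was not tested.

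The replicate numbers of the labels are only shared numbers: the difference between replicates 1 and 2 correlated at 0.154 across probe sets between genotypes, and there are only 2 pairs. With the replicate block the cholesterol list had a median of -0.87 (camera adjusted p = 4.7e-09 at the preset correlation, against 0.902 at an estimated one without the block) and was again the 1 list called. With it 126 probe sets passed the unadjusted threshold and 0 the adjusted one, and 0 genes within 20 Mb of Avpr1a passed the unadjusted one.

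The odds ratio near Avpr1a was 0 without a filter, with the replicate block and within 5 Mb, 0.788 within 40 Mb, and 0 to 2.85 leaving out each array. List medians near 0 that turned their sign were, without a filter, circadian clock -0.0043, cell cycle -8.7e-05 and interferon-stimulated genes -0.034. Under the stricter filter they were fatty acid oxidation -0.0016, endothelium -0.060 and the Avpr1a neighbours -0.019. With quantile normalization they were ACTH and cAMP signalling 0.018, chromaffin cells 0.044 and the gene Th 0.045, and with centring 0.019, 0.0051 and 0.0051. With plain probe sets they were the circadian clock -0.035 and the Avpr1a neighbours -0.040, and with gene means zona glomerulosa -0.021, circadian clock -0.035, interferon-stimulated genes -0.090 and endothelium -0.13.

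Leaving out each array in turn, the cholesterol list ranged from -0.94 to -0.76. Medians of either sign were reached by cholesterol ester and lipid droplet handling (-0.18 to 0.16), the renin-angiotensin system (-0.072 to 0.11), vasopressin and Gq signalling (-0.084 to 0.028), ACTH and cAMP signalling (-0.25 to 0.20), chromaffin cells (-0.41 to 0.35), immediate-early genes (-1.27 to 0.40), adipocytes (-1.17 to 0.59), Schwann and glial cells (-0.45 to 0.29) and zona glomerulosa (-0.14 to 0.16). So were those of the circadian clock (-0.053 to 0.14), macrophages (-0.046 to 0.24), interferon-stimulated genes (-0.47 to 0.45), endothelium (-0.26 to 0.12), the Avpr1a neighbours (-0.044 to 0.095), capsule and fibroblasts (-0.44 to 0.0060) and fatty acid oxidation (-0.066 to 0.13). Genes that did so were Star (-0.022 to 0.090), Cyp11a1 (-0.046 to 0.051), Cyp11b1 (-0.032 to 0.26), Cyp21a1 (-0.27 to 0.029), Cyp11b2 (-0.11 to 0.47), Th (-0.52 to 0.49), Dbh (-1.11 to 0.50), Alas2 (-4.47 to 0.12), Bpgm (-1.42 to 0.29), Cpb1 (-0.30 to 0.64), Kdm5d (-0.15 to 0.49) and Uty (-0.45 to 1.87). Other named genes kept their sign but moved widely, among them Camk2d (0.56 to 3.14), Adcy9 (0.28 to 1.39) and Insm1 (0.59 to 2.93). So did Pnmt (-1.51 to -0.030), Ighm (0.67 to 3.54), Thy1 (-1.73 to -0.25), Aqp1 (-1.36 to -0.31) and Fxyd2 (-1.86 to -0.018). Rgs5 ranged from 0.27 to 0.78 and Cela1 from -0.77 to -0.0063. The cause of these turns and moves was not tested.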

Other observations

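The tests in this part were chosen after the results were seen, with these exceptions. Those on gene families and on single probe sets of wild-type array 1 were not chosen so. The tests of the cholesterol list without wild-type array 1 and with an estimated correlation had been fixed before the data were examined.

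Some of the larger differences, none of which passed the adjusted threshold in limma, were read from genes beside one another on a chromosome. Mmp2 and its neighbour Lpcat2 on chromosome 8 differed by -2.32 and -2.58. Ppt1, a lysosomal thioesterase, and the overlapping gene Cap1, a regulator of actin, on chromosome 4 differed by -1.19 and -3.93. At the end of chromosome 13, Tmem267 differed by 3.88 and Hmgcs1 by -1.44, and in the same stretch 1 probe set of Nnt, the mitochondrial transhydrogenase, by -1.06 and another by 0.31.

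The lower cholesterol synthesis list in the knockout was not set by wild-type array 1 alone, since the median was -0.90 without it. Of 10000 random lists matched on mean level 0 were as low (lowest -0.36), though random lists leave out the correlation between members. In camera with an estimated correlation the call was lost (adjusted p = 0.902). That test has only 2 residual degrees of freedom, so the loss cannot be laid to the correlation alone. A smaller share of cortex in the knockout glands would lower the steroidogenic genes as much, and the 7 of these under 12 log2 units had a median of -0.11 (95% bootstrap interval -0.38 to 0.02). The lowest of the 7 was Mrap at -0.45. The median gene, Nr0b1, read 4.05 to 4.22, close to the filter. The interval resamples genes and not glands, so it does not measure how the share of cortex varied between samples. The 3 splits of the 4 arrays into 2 and 2 are too few for a share under 0.05, with 1 of 3 as far from 0, a real median of 0.87 in size and 0.19 in the highest other split. The genotype, feeding, hour of sampling and strain stay open as explanations and were not tested. Of 14 further probe sets in 10 of the list's genes 8 were lower, with a median of -0.30, and without wild-type array 1 11 were lower, with a median of -0.43.

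The genes past the unadjusted threshold lay near one another more often than random sets: 30 of 70 had another within 2 Mb, against a median of 12 in 10000 random sets (permutation p = 0.0002), and 3 and 8 of 70 top genes in the other splits. The 30 formed 13 clusters on 9 chromosomes, 7 of them with both directions, and chromosomes 1, 2 and 16 held 0 of 70, where 4.01, 5.47 and 2.27 would be drawn by chance (permutation p = 0.004 for the spread over chromosomes). These counts took 1 probe set per gene, so chromosome 2 was not free of such differences. Probe sets of Sdc4 (-1.86) and Cd59a (-2.03) on chromosome 2, which did not stand for their genes, passed the unadjusted threshold. Only 1.43% of the 70 lay within 20 Mb of Avpr1a, which argues against flanking DNA alone as the cause. Only 6.67% of the 30 had a neighbour of the same gene family, judged by symbol, and sequences were not compared, so shared sequence was not tested further. The other probe sets of a gene showed a median of 0.703 of the first one's difference (95% bootstrap interval 0.540 to 0.885). That argues against variants under single probe sets as the whole cause, for the 20 of the 70 genes it covers. Among the explanations left open is that stretches of the genome may have come from different strains in the 2 genotypes, a hypothesis that the arrays do not test further. The count itself was 144 probe sets in the real split and 73 in the highest other split, with 1 of 3 splits as large, too few splits for a share under 0.05.

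Wild-type array 1 had 551 tested probe sets at least 2 log2 units from the mean of the other 3 arrays, 473 lower and 78 higher, where the other arrays had 15 to 31 lower and 18 to 24 higher. RNA from liver may be present on this array: the 9 probe sets of Alb, Apoa1 and Ttr, from the fixed liver list, were a median of 4.37 above the other arrays (2.25 to 6.44). All 9 failed the filter, so they are not among the 78 and do not show what those are. These genes were also chosen after their values were seen. The lower probe sets made up 85.8% of the 551, but this share cannot tell whether outside tissue played a part. A probe set high only on wild-type array 1 fails the filter, while one low only there passes it. The lower ones were mostly readings of single probe sets, since the other tested probe sets of the same genes had a median of -0.14 against -2.63. Of the lower ones 51.4% had an extended suffix, against 31.9% of all. Degraded RNA cannot be told apart from intact RNA by the controls, as the 3' minus 5' difference of actin was the lowest of the 4 arrays at 2.12 and that of Gapdh the highest at 0.80; no biological explanation was tested.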
